A study of Mus musculus with 6 samples.

How the data were processed

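The deposited table held 1 value per probe set and array for 6 microarrays, 3 labelled WT and 3 labelled KO, each from a different mouse. Per the labels, total RNA from inguinal subcutaneous white fat was labelled with biotin using a GeneChip WT Pico kit. The submitters' processing notes name Transcriptome Analysis Console, without a version. The deposited values are log2 signals per probe set. Their scale was tested on the table itself: values ran from 2.81 to a ceiling of 19.93, and 222 probe sets stood at that ceiling on all 6 arrays and 334 on at least 1. Medians per array lay between 6.47 and 7.02, so the 6 distributions were not brought to one common shape. The background correction, the normalization and the summary method are not given in the sources used here. No detection calls, scanner files or scan dates were available, so a level above background could not be tested, and no batch could be examined.

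All 65956 probe sets were tested. GEO's annotation of the array, with symbols updated through the RefSeq gene table of GRCm38.p6, paired 31269 of them with exactly 1 gene symbol, 1481 with several and 33206 with none. Those without a single symbol stayed unnamed. The authors' genome build is not given in the sources used here, so no coordinates are printed. The 30712 named genes were each represented by the probe set with the highest mean over the 6 arrays, and 442 genes had several probe sets. Values of 1816 probe sets repeated those of another probe set on all 6 arrays.

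Arrays labelled KO were compared with those labelled WT by limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend, on the values as deposited, with genotype as the only term and Benjamini-Hochberg adjustment over all probe sets. An adjusted p under 0.05 counted as a call. Tfg was also compared by an exact 2-sided permutation test of 3 against 3 values, in scipy 1.17.1. Its smallest possible p is 0.1. The design, the alternatives and 34 gene lists of 745 genes were fixed before the data were examined. Of these genes 677 were measured, and the others were not analysed here. Some genes stand in several lists, so the lists are not independent of each other. Lists of at least 5 measured genes were tested against all other named genes with limma's camera, with the inter-gene correlation preset at 0.01 and adjustment over the 33 lists tested. Counts within a list are given after adjustment over all probe sets and adjusted over the list alone.

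Genes were named by a fixed rule. It took Tfg, the 12 largest rises and the 12 largest falls among called genes without overlap between the groups, and up to 4 members of each list with the smallest p. Adipoq, Lep, Pparg, Cebpa, Ucp1, Fasn, Hspa5, Thra and Thrb were always named. Predicted genes and immunoglobulin or T cell receptor segments were counted but not named. Classes of probe sets (ribosomal protein genes, olfactory and vomeronasal receptors, small RNAs) and 16 measured housekeeping genes were chosen after the values had been seen. The housekeeping genes had a median of 7.86 on WT-labelled arrays. Only the adipocyte, PPARG and lipolysis lists had higher medians there. For the other lists a change relative to the housekeeping genes therefore also compares dimmer with brighter genes.

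The procedure was tested on simulated arrays with 200 changed probe sets. At 3 arrays per group limma recovered 20% of changes of 1 on the log2 scale, 52% of changes of 2 and 90% of changes of 3, and 16% of changes of -1, with 3 false calls among 65956 probe sets. Noise was drawn independently for each probe set, and far fewer probe sets changed than the 13791 called in the data. The cutoff after adjustment was therefore stricter there, and these rates do not carry over to the data. The list test called the 1 list shifted by 1 and 0 of 32 others. Genes were drawn independently there, so this says nothing about false calls among correlated genes. In the data the estimated correlation within a list reached 0.77 for adipocyte and 0.81 for skeletal muscle markers. The alternatives covered quantile normalization, centring each array on its median, leaving out dim probe sets (mean under 6.43 or under 6.83), eBayes with trend and with trend and robust, array weights, the replicate number as a block, probe sets with 1 gene symbol, other thresholds, leaving out each array in turn, an estimated inter-gene correlation, limma's fry (which tests whether a list moves, not whether it differs from other genes), and the mean of a gene's probe sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots, and statmod 1.5.0 supported limma. The number of arrays limits the precision of every value.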

Results

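Whole-transcript microarrays measured RNA in inguinal subcutaneous white fat of male C57BL/6 mice aged 2 months. In the KO group, 3 mice carried floxed Tfg alleles and a tamoxifen-inducible Cre recombinase under the adiponectin promoter. In the WT group, 3 mice carried the floxed alleles without Cre. Tamoxifen was given for 5 days and the fat was taken 2 weeks after it. Each array gave log2 signals of 65956 probe sets, and means below are over n = 3 arrays per group. The median signal was 6.97, 6.96 and 7.02 on the WT arrays and 6.76, 6.47 and 6.73 on the KO arrays. WT arrays correlated with each other at 0.984 to 0.986 across probe sets. KO 1 and KO 3 correlated at 0.986, while KO 2 correlated with them at 0.96 and 0.965.

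The comparison asked which transcripts differ in fat when Tfg, which encodes a protein of the endoplasmic reticulum exit sites, is deleted in adipocytes. Tfg itself was not lower on the arrays labelled KO. Its log2 signal was 7.97, 7.94 and 7.91 on the WT arrays, 7.94 ± 0.03 (SD, n = 3). It was 7.99, 8.21 and 8.03 on the KO arrays, 8.08 ± 0.12 (SD, n = 3). The difference of 0.14 ± 0.11 (SE) did not pass limma's test (adjusted p = 0.345). The exact 2-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. Relative to the mean of 16 housekeeping genes, which was 1.24 higher on the KO arrays, Tfg stood at -1.12 ± 0.13 (SD) on WT and -2.23 ± 0.26 (SD) on KO arrays, again with an exact permutation p of 0.1. Among 3308 protein-coding genes of similar level its change lay at the 39.3rd percentile. Which exons the Tfg probe set reads is not given, so it checks the labels only in part, and the groups are called KO-labelled and WT-labelled arrays from here on.

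Many genes of the fat cell and of fat metabolism stood far higher on the KO-labelled arrays. Fasn, which encodes fatty acid synthase, rose by 6.38 ± 0.87 on the log2 scale (SE), or 83.3-fold. Pparg, the master transcription factor of adipocytes, rose 12.6-fold and the adiponectin gene Adipoq 7.60-fold. Endothelial Cdh5 rose 16.6-fold, and 35 of 40 measured respiratory chain genes rose. Housekeeping genes (median change 1.11) and 43 ribosomal protein genes (median change 0.97) were higher too. In contrast, 1086 olfactory and 300 vomeronasal receptor genes read lower, with a median change of -0.82 in each class. The olfactory receptor genes had a median of 7.47 on WT-labelled arrays. Without detection calls, folds of genes near that level there, such as Cdh5 (7.01), Pparg (7.90) and Fasn (8.02), are uncertain.

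limma called 13791 probe sets, 3509 higher and 10282 lower on the KO-labelled arrays. Among 19533 protein-coding probe sets it called 2082 higher and 1987 lower. Among 3426 long noncoding RNA probe sets it called 14 higher and 687 lower, and among 959 small nucleolar RNA probe sets 30 higher and 280 lower. Over all probe sets, the 3 KO-labelled values lay all above the 3 WT-labelled values in 11.1% and all below them in 44.9%. Chance gives 5% in each direction for any given probe set if the arrays are exchangeable. Probe sets share the same arrays, whose medians differ, so a shift of whole arrays can move many together. These shares are therefore descriptive and cannot be tested against 5%. The median change of all probe sets was -0.37, and of protein-coding probe sets -0.18. Changes are given as deposited, so a gene at 0 lay 0.37 above the median probe set. The share of calls that were higher was 25.4% on the deposited values, 64.6% after quantile normalization and 61.2% after centring each array on its median. Of the 98 named genes that rose, 24 rose by less than the housekeeping mean of 1.24. The smallest adjusted p was 0.0305, close to the threshold. Without WT 1, WT 2, WT 3 or KO 3 limma called 0 probe sets, with 23757, 25102, 21579 and 28697 at an unadjusted p under 0.05.

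**Figure D1:**
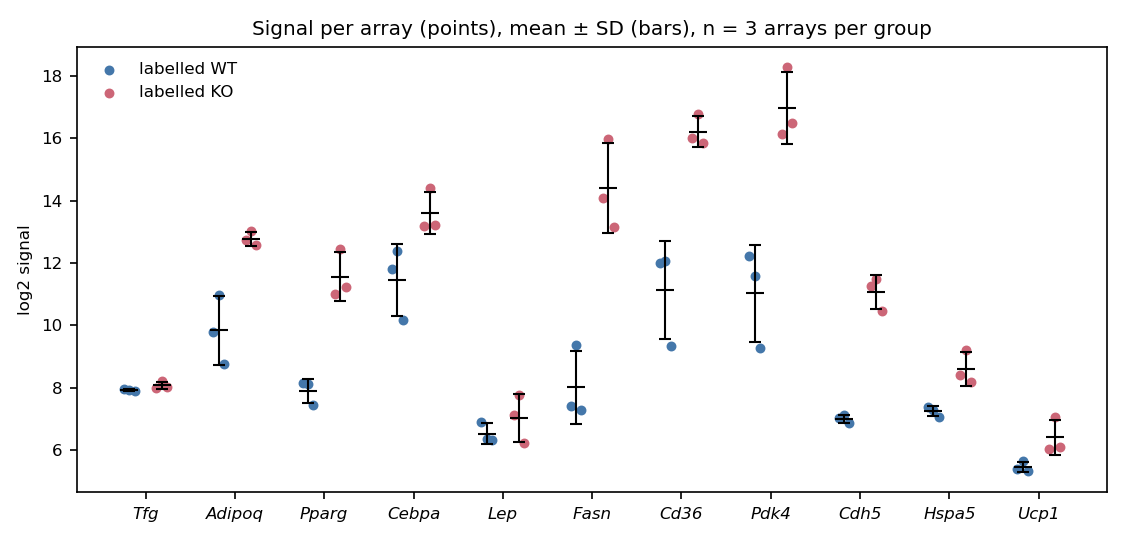
Log2 signal (vertical axis) of 11 genes on each WT-labelled and KO-labelled array (points), with the mean and SD of 3 arrays (bars). Tfg was 7.94 on WT-labelled and 8.08 on KO-labelled arrays, while Fasn was 8.02 and 14.40.

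After Fasn the largest rise was in Pdk4. This gene, which encodes a kinase that restrains pyruvate oxidation, rose by 5.93 ± 0.90 (SE), or 61.1-fold. Cyp2e1, a cytochrome P450 gene, rose by 5.72 ± 0.58. Cd36, which encodes a fatty acid transporter, rose by 5.07 ± 0.77, from 11.13 ± 1.56 (SD) to 16.20 ± 0.49. The retinol-binding protein gene Rbp7 rose by 5.20 and Pde3b, which encodes the phosphodiesterase through which insulin restrains lipolysis, by 4.92. B2m, the light chain of major histocompatibility complex class I, rose by 4.83, the resistin gene Retn by 4.55, Ivns1abp by 4.60 and Serinc3 by 4.54. The pseudogenes Ndufa12-ps and Glns-ps1 read 4.83 and 4.71 higher, but resemble expressed parent genes and are uncertain. Adjusted p values of the 12 largest rises lay between 0.0346 and 0.0356.

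Of 23 adipocyte markers 14 rose and 0 fell, or 20 and 0 adjusted over the list alone. Their median change was 2.60, and 1.36 relative to the housekeeping genes (camera adjusted p = 4.34e-15, and adjusted p = 0.201 with an estimated correlation). Pparg went from 7.90 ± 0.39 (SD) to 11.56 ± 0.78, and Adipoq from 9.84 ± 1.11 to 12.77 ± 0.22. The lipid droplet coat gene Plin1 rose by 2.29, the glycerol channel gene Aqp7 by 3.31 and adipogenin, Adig, by 2.31. Cebpa was 2.15 higher without passing (adjusted p = 0.055), and the leptin gene Lep, at 6.53 ± 0.34 and 7.04 ± 0.76, overlapped between the groups (adjusted p = 0.328). Of 22 PPARG targets 15 rose and 0 fell, or 20 and 1 over the list alone, with a median change of 2.42 (camera adjusted p = 1.18e-14, and adjusted p = 0.201 with an estimated correlation). The fatty acid binding protein gene Fabp5 rose 3.95-fold. The PPARG list shares genes such as Adig, Aqp7 and Plin1 with the adipocyte list, so the lists are not separate evidence. Housekeeping genes rose beside these lists, by a median of 1.11.

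In the lists of fatty acid and triglyceride synthesis and of lipolysis, many genes rose and none fell. Of 17 fatty acid synthesis genes 8 rose and 0 fell, or 13 and 0 adjusted over the list alone, with a median change of 1.86. Acaca, which encodes acetyl-CoA carboxylase 1, rose 13.3-fold, the lipogenic regulator Thrsp 19.6-fold and the elongase gene Elovl5 4.52-fold. Of 15 triglyceride synthesis genes 11 rose and 0 fell, or 12 and 0 over the list alone, with a median change of 1.41. Pck1, a glyceroneogenesis enzyme gene, rose 15.2-fold, Gpd1 12.7-fold, the acyltransferase gene Dgat1 3.58-fold and the seipin gene Bscl2 1.79-fold. Of 14 lipolysis genes 12 rose and 0 fell, or 13 and 0 over the list alone, with a median change of 2.37. The protein kinase A subunit gene Prkar2b rose 11.1-fold. The camera adjusted p of these lists was 7.07e-10, 7.77e-09 and 7.72e-12, and with an estimated correlation the adjusted p was 0.201 for each. Relative to the housekeeping genes their medians were 0.62, 0.17 and 1.13. With the housekeeping mean of each array as a covariate the fatty acid synthesis list turned down against other genes (adjusted p = 0.00127). That covariate separates the labels completely, at 8.91 to 9.2 on WT-labelled and 10.06 to 10.74 on KO-labelled arrays. A fit with it therefore cannot tell the genotype from the housekeeping signal, here or below. No conclusion is drawn from the direction a list takes with it, and no probe set passed (smallest adjusted p = 0.727).

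Cholesterol synthesis genes had no common direction. Of 19 genes 2 rose and 1 fell, the same as over the list alone. Their median was -0.10 and their mean 0.16, and camera pointed up without passing (adjusted p = 0.273). After centring on the median the list's median was 0.23 and it passed (adjusted p = 0.0209). Its mean change against other genes was 0.32 before and after centring. With an estimated correlation, on the deposited values, the adjusted p was 0.376. Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose by 3.28 ± 0.20 (SE), with the smallest adjusted p of all (0.0305). The squalene synthase gene Fdft1 rose 1.96-fold, Fdps fell by 0.47 on the log2 scale (-0.10 against the median probe set), and Mvd, at a change of -0.41, did not pass (adjusted p = 0.0711).

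Most genes of the respiratory chain and of fatty acid oxidation rose. Of 40 respiratory chain genes 35 rose and 0 fell, or 36 and 0 adjusted over the list alone. Their median change was 2.19, and 0.94 relative to the housekeeping genes (camera adjusted p = 2.31e-24, and adjusted p = 0.201 with an estimated correlation). The cytochrome c oxidase genes Cox4i1, Cox7c and Cox6c rose 4.99-fold, 2.66-fold and 2.08-fold, and the complex I gene Ndufa2 12.5-fold. Of 23 fatty acid oxidation genes 19 rose and 0 fell, or 20 and 0 over the list alone, with a median change of 1.70 (camera adjusted p = 1.79e-14, and adjusted p = 0.201 with an estimated correlation). Acadl rose 13.0-fold, Hadha 7.52-fold, Ehhadh 5.76-fold and the carnitine carrier gene Slc25a20 4.50-fold. Relative to the housekeeping genes the median of this list was 0.46. Of 24 thermogenic genes 3 rose and 0 fell, or 1 and 0 over the list alone, with a median change of 0.14 and of -1.10 relative to the housekeeping genes (camera adjusted p = 0.0136, and adjusted p = 0.201 with an estimated correlation). Cox8b rose 11.6-fold, Cox7a1 2.32-fold and Cpt1b 1.73-fold. Ucp1, the uncoupling protein gene, was 0.95 higher and Cidea 1.49 higher without passing (adjusted p = 0.06 and 0.0506). These lists turned down against other genes with the housekeeping covariate (adjusted p = 0.0169, 0.00246 and 0.00246), which separates the labels completely and so decides nothing here. The fast muscle gene Atp2a1 was higher on KO 1 and KO 2 but read 7.12 on KO 3, where Cox8b read 9.16.

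In the pathway in which TFG acts, most genes did not pass. Of 33 genes of COPII coats and transport from the endoplasmic reticulum to the Golgi 10 rose and 0 fell, or 15 and 0 adjusted over the list alone. Their median change was 0.47, but -0.77 relative to the housekeeping genes (camera adjusted p = 2.16e-09, and adjusted p = 0.201 with an estimated correlation). The housekeeping genes were brighter, with a median of 7.86 on WT-labelled arrays against 7.18 for this list. The 3308 protein-coding genes near the level of Tfg had a median change of 0.33. Sec31a, of the outer COPII coat, rose by 1.11 ± 0.21 (SE), the retrieval receptor genes Kdelr2 and Kdelr1 by 1.07 ± 0.16 and 0.78 ± 0.14, and the cargo receptor gene Lman1 by 0.83 ± 0.18. With the housekeeping covariate, which separates the labels completely and so decides nothing here, the list turned down against other genes (adjusted p = 0.00359). Among expressed genes only, with 7 of its genes left, the list did not pass (mean change against other genes 0.57, against 0.66 before, adjusted p = 0.103). Of the 33 genes 26 had a change above that of Tfg, while Kdelr3 and Sec31b, chosen after their values were seen, stood at -0.28 and -0.22 without passing. Of 31 unfolded protein response genes 9 rose and 0 fell, or 17 and 0 over the list alone, with a median change of 0.46 and of -0.79 relative to the housekeeping genes (camera adjusted p = 2.16e-09, and adjusted p = 0.201 with an estimated correlation). Among expressed genes only, with 7 of its genes left, this list did not pass (mean change against other genes 1.31, against 0.90 before, adjusted p = 0.0528). With the housekeeping covariate it pointed down without passing (adjusted p = 0.0581). The chaperone gene Hspa5 rose by 1.35 ± 0.28 (SE), from 7.25 ± 0.16 (SD) to 8.61 ± 0.54. Hsp90b1 rose 5.62-fold, the disulfide isomerase gene Pdia3 from 7.59 ± 0.07 (SD) to 9.59 ± 0.64, Dnajb9 3.61-fold and the transcription factor gene Atf4 2.41-fold.

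Members of hormone response, adipokine and lysosome lists also rose, some of them counted in lists above. Thrsp and Me1 of the thyroid list are also fatty acid synthesis genes, and Pde3b of the insulin list is a lipolysis gene. Adipoq and Retn of the adipokine list are adipocyte markers. Of 23 thyroid hormone genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone, with a median change of 0.30 (camera adjusted p = 0.000324, and adjusted p = 0.227 with an estimated correlation). The malic enzyme gene Me1 rose 18.6-fold, Sult1a1 4.43-fold and Idh3a 3.13-fold, while the receptor genes Thra and Thrb were 0.34 and 0.33 higher without passing (adjusted p = 0.114 and 0.227). Of 18 insulin signalling genes 7 rose and 0 fell, or 8 and 0 over the list alone, with a median change of 0.57 (camera adjusted p = 2.33e-08, and adjusted p = 0.227 with an estimated correlation). Irs2 rose 6.02-fold, Foxo1 3.21-fold and Igf1 1.68-fold. Of 23 secreted adipokine genes 7 rose and 1 fell, the same as over the list alone, with a median change of 0.37 (camera adjusted p = 0.00124, and adjusted p = 0.201 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, rose 5.23-fold and Apoe by 1.59 on the log2 scale. Of 23 autophagy and lysosome genes 11 rose and 0 fell, or 14 and 0 over the list alone, with a median change of 0.60 (camera adjusted p = 8.40e-10, and adjusted p = 0.201 with an estimated correlation). The cathepsin genes Ctsb and Ctsl rose 23.0-fold and 6.31-fold, Gabarapl1 12.6-fold and Lamp1 7.11-fold. Relative to the housekeeping genes, which were brighter than these lists, their medians turned negative, at -0.95, -0.68, -0.88 and -0.64. The thyroid and insulin lists turned down against other genes with the housekeeping covariate (adjusted p = 0.00359 for each), which separates the labels completely and so decides nothing here.

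**Figure D2:**
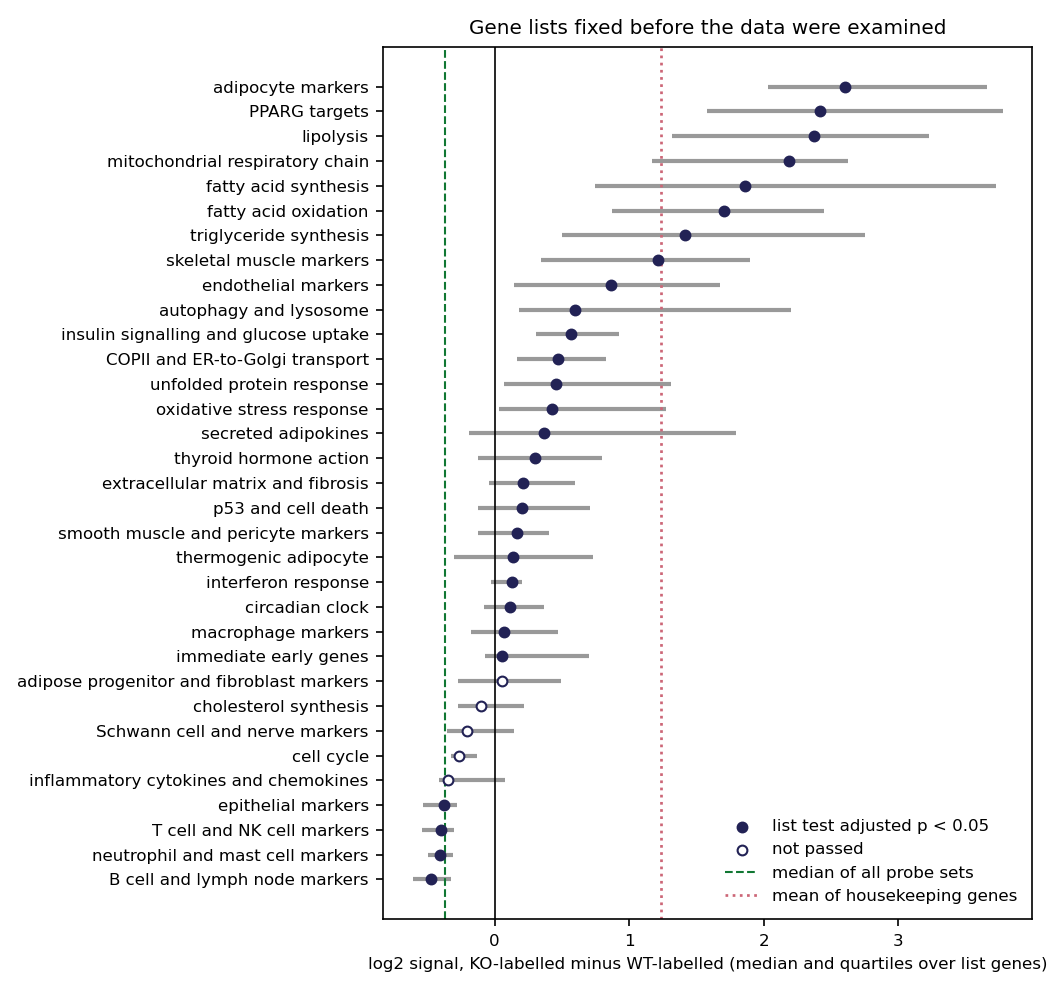
Median (points) and quartiles (lines) of the change in log2 signal, KO-labelled minus WT-labelled, over the members of 33 gene lists, with filled points where camera passed on the deposited values. Vertical lines mark 0, the median of all probe sets at -0.37 and the housekeeping mean at 1.24, relative to which lists to the left of it read lower.

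Markers of cell types other than adipocytes also moved. Of 19 endothelial markers 12 rose and 0 fell, or 13 and 1 adjusted over the list alone, with a median change of 0.86 and of -0.38 relative to the housekeeping genes (camera adjusted p = 1.87e-09, and adjusted p = 0.201 with an estimated correlation). Cdh5, which encodes vascular endothelial cadherin, went from 7.01 ± 0.13 (SD) to 11.07 ± 0.55, and the receptor genes Kdr and Ptprb rose 5.58-fold and 6.25-fold, and Pecam1 5.22-fold. Of 31 extracellular matrix genes 6 rose and 0 fell, or 7 and 0 over the list alone, with a median change of 0.21 and of -1.03 relative to the housekeeping genes (camera adjusted p = 2.00e-06, and adjusted p = 0.162 with an estimated correlation). Postn rose 10.1-fold, Sparc 5.22-fold, Bgn 2.65-fold and the basement membrane collagen gene Col4a2 1.61-fold. Of 25 macrophage markers 4 rose and 1 fell, the same as over the list alone, with a median change of 0.07 and of -1.17 relative to the housekeeping genes (camera adjusted p = 0.00382, and adjusted p = 0.303 with an estimated correlation). The call was lost without the dimmer probe sets (mean under 6.83, adjusted p = 0.101) and under fry, which tests a list against no change (adjusted p = 0.172). Without the dimmer probe sets the mean change against other genes was 0.27, against 0.36 before. Lyz2 rose 3.05-fold, Mertk 2.77-fold, Fcer1g 1.83-fold and the complement gene C1qb 1.75-fold. Of 15 smooth muscle and pericyte markers 3 rose and 0 fell, the same as over the list alone, with a median change of 0.16 and of -1.08 relative to the housekeeping genes (camera adjusted p = 0.00491, and adjusted p = 0.231 with an estimated correlation). Rgs5 rose 3.82-fold, Acta2 2.53-fold and Abcc9 1.99-fold.

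Of 23 progenitor and fibroblast markers 2 rose and 2 fell, the same as over the list alone, and camera did not pass (median change 0.05, adjusted p = 0.0567). It passed after quantile normalization and after centring (adjusted p = 0.0114 and 0.0183), without the dim probe sets (0.0267 and 0.00814), and without WT 1, WT 3 or KO 3 (0.0386, 0.0395 and 0.0378). With an estimated correlation the adjusted p was 0.201. Dcn rose 5.00-fold and Ly6c1 3.17-fold, while Clec11a and Sfrp2 fell by 0.68 and 0.48 (-0.31 and -0.11 against the median probe set). Of 20 skeletal muscle markers 0 passed, over all probe sets and over the list alone, although the list's median change was 1.22 (camera adjusted p = 0.000145, and adjusted p = 0.405 with an estimated correlation). Atp2a1, the calcium pump gene of fast muscle, read 7.19, 7.08 and 7.36 on WT-labelled arrays and 11.20, 13.39 and 7.12 on KO-labelled arrays, and Acta1 read 9.59, 11.79 and 7.80 on KO-labelled arrays. The mean change of the list against other genes, 1.40, became 0.68 without KO 2 and 2.13 without KO 3. With the housekeeping covariate, which separates the labels completely and so decides nothing here, the list turned down (adjusted p = 3.66e-06).

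Some lymphocyte, granulocyte and epithelial markers fell, on arrays where 15.6% of all probe sets and 10.2% of protein-coding ones were called lower. Unnamed probe sets had a median change of -0.45, near the medians of these lists. No loss of these cell types is therefore inferred. Of 17 T cell and NK cell markers 0 rose and 4 fell, or 0 and 10 adjusted over the list alone, with a median change of -0.40 that became -0.07 after centring each array on its median (camera adjusted p = 0.00491, adjusted p = 0.0227 after centring, and adjusted p = 0.405 with an estimated correlation). Klrb1c fell by 1.10, Cd3g by 0.74, Cd28 by 0.67 and Cd2 by 0.54 (-0.73, -0.37, -0.31 and -0.18 against the median probe set). Of 18 B cell and lymph node markers 0 rose and 6 fell, or 0 and 8 over the list alone, with a median change of -0.47 that became -0.14 after centring (camera adjusted p = 0.00671, adjusted p = 0.00812 after centring, and adjusted p = 0.456 with an estimated correlation). Ccl19 fell by 0.83, Fcer2a by 0.65, Cd22 by 0.61 and Cd79a by 0.52 (-0.47, -0.29, -0.25 and -0.15 against the median probe set). Of 17 neutrophil and mast cell markers 0 rose and 5 fell, the same as over the list alone, with a median change of -0.40 that became -0.07 (camera adjusted p = 0.0191, adjusted p = 0.106 after centring, and adjusted p = 0.405 with an estimated correlation). The mean change of this list against other genes was -0.26 before and after centring. Cpa3 fell by 0.79 and Ly6g by 0.79 (-0.42 and -0.43 against the median probe set). Of 20 epithelial markers 0 rose and 3 fell, the same as over the list alone, with a median change of -0.38 that became -0.05 (camera adjusted p = 0.0191, adjusted p = 0.122 after centring, and adjusted p = 0.54 with an estimated correlation). Against other genes the mean change of the epithelial list stayed at -0.25 after centring. Csn3 fell by 0.92, Krt14 by 0.69 and Prom2 by 0.53 (-0.55, -0.33 and -0.16 against the median probe set).

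The 12 largest falls held 8 vomeronasal receptor genes or pseudogenes, Vmn1r159, Vmn1r121, Vmn1r160, Vmn1r142, Vmn1r113, Vmn1r-ps74, Vmn1r-ps71 and Vmn1r-ps80, which fell by 2.35 to 2.66 on the log2 scale. Vmn1r159 went from 12.58 ± 1.02 (SD) to 9.92 ± 1.15. The olfactory receptor gene Olfr476 fell by 2.43 ± 0.34 (SE), the spliceosomal RNA gene Rnu6 by 2.52 ± 0.68, and the microRNA genes Mir669h and Mir466o by 2.40 ± 0.66 and 2.37 ± 0.62. These genes have near-identical copies, so their signals are uncertain, and other probe sets of Mir669h, Mir466o and Rnu6 read 1.29, 1.36 and 1.29 lower. Adjusted p values of the 12 were 0.0354 or higher, and under 0.05. The median change of olfactory and vomeronasal receptor genes, -0.82, compares with -0.37 for all probe sets.

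**Figure D3:**
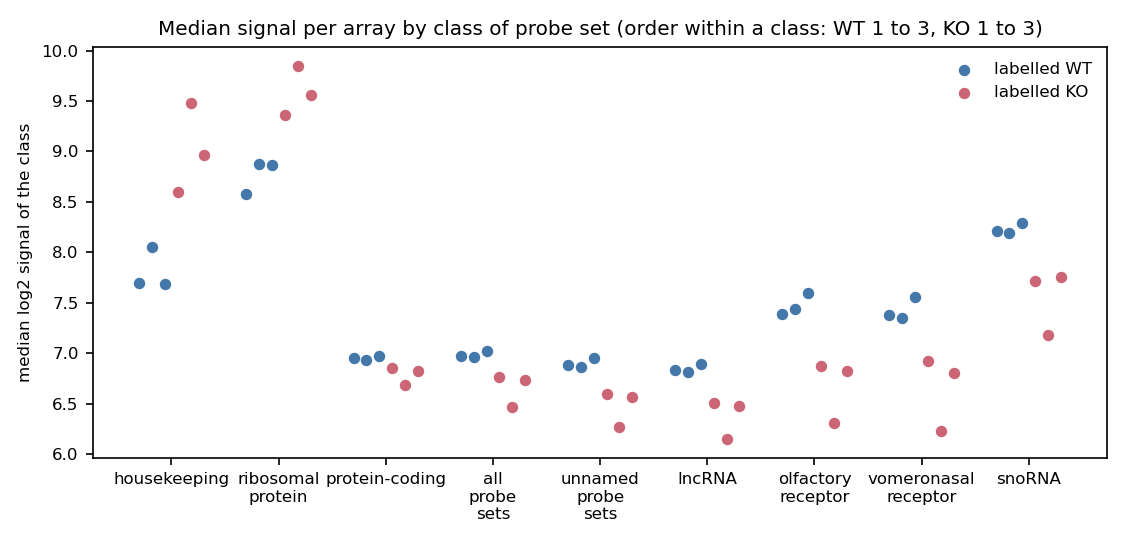
Median log2 signal (vertical axis) of classes of probe sets on each of the 6 arrays (points, coloured by the label of the array). Housekeeping genes read 7.70, 8.05 and 7.69 on WT-labelled and 8.60, 9.48 and 8.96 on KO-labelled arrays, and olfactory receptor genes 7.39, 7.44 and 7.60 against 6.87, 6.31 and 6.82.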

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

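Housekeeping scaling (subtracting each array's housekeeping mean), the housekeeping covariate, the list test on expressed genes only and the omission of probe sets at the ceiling were chosen after the data had been seen. The Tfg change stayed positive and short of the threshold under every alternative fixed in advance, from 0.07 to 0.18 when 1 array was left out and up to 0.47 after centring. It turned to -1.11 under housekeeping scaling (adjusted p = 0.00574), which lowers every gene by construction, and to -0.22 with the housekeeping covariate (adjusted p = 0.899). The count of higher probe sets, 3509, became 653 under housekeeping scaling, 0 with the covariate, 5902 at adjusted p under 0.1 and 0 at adjusted p under 0.01. The count of lower ones, 10282, became 2212 after quantile normalization, 3259 after centring, 17432 with array weights, 6774 among probe sets with 1 gene symbol, 60325 under housekeeping scaling, 0 with the covariate, 24774 at adjusted p under 0.1 and 0 at adjusted p under 0.01. With the covariate limma had 4462 probe sets at an unadjusted p under 0.05, against 31589 without it. Leaving out 1 array gave 0 to 3469 higher and 0 to 10697 lower probe sets. The count was 0 without WT 1, WT 2, WT 3 or KO 3, with smallest adjusted p of 0.0997, 0.0824, 0.114 and 0.0624, with fewer arrays in each fit. It was 3046 higher and 6921 lower without KO 2. The 13791 probe sets had an unadjusted p under 0.05 whichever array was left out, but they had been chosen by their p in the fit of all arrays. That result was therefore largely set by the selection. Their sign could not change, since the groups did not overlap in them. The replicate numbers did not pair the samples (correlations of same-numbered deviations 0, 0.2 and 0.14, and not every array matched its own number best), and the replicate block gave 2960 higher and 8267 lower.

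Of 33 lists 28 were called, 24 up and 4 down, and 28 or 29 when 1 array was left out. Lists share genes, so these calls are not independent. With an estimated correlation 0 were called, while fry, which tests a list against no change and not against other genes, called 23. The lists that fry no longer called were thermogenic, thyroid hormone, adipokine, macrophage, smooth muscle, skeletal muscle and clock genes, and it gained the cell cycle list, down (adjusted p = 0.0263). On expressed genes only 9 of 18 were called, all up: respiratory chain, adipocyte markers, PPARG targets, lipolysis, fatty acid oxidation, autophagy, endothelial markers, fatty acid synthesis and triglyceride synthesis. With the housekeeping covariate 13 were called, 2 up (macrophage and endothelial markers) and 11 down (COPII transport, fatty acid synthesis, thermogenic, thyroid hormone, respiratory chain, fatty acid oxidation, insulin signalling, oxidative stress, skeletal muscle, Schwann cell and clock). These calls decide nothing about the genotype, because the labels are separated completely by the covariate. With it 63 of the 156 named genes changed sign, at a smallest adjusted p of 0.727 over all probe sets. With the replicate block the progenitor list was called (adjusted p = 0.0483). The Schwann cell list turned down under fry (mean change 0.15, adjusted p = 0.0263), and its median and mean already differ in sign. In the other alternatives, genes that turned positive without passing were Myh7 (0.059 after quantile normalization, 0.037 after centring), Bpgm (0.113 and 0.077) and Alas2 (0.162 and 0.21, 0.004 with array weights, and 0.007 without KO 2 in a range of -0.198 to 0.007 when 1 array was left out). The cause was not tested. Centring moved the median change of all probe sets from -0.37 to -0.04. The call was lost for 33 named genes after quantile normalization, 22 after centring and 25 with the replicate block. With single arrays left out, 569 combinations of named gene and array lost the call, 2 gained it and 358 stayed on the same side of the threshold, all in the same direction, which is fixed where the groups do not overlap, and 1 changed sign (Alas2 without KO 2). Background is unknown without detection calls. The olfactory receptor median on WT-labelled arrays was 7.47. Folds of genes near or below it, such as Thrsp, Cdh5, Cox8b and Fasn (6.76, 7.01, 6.51 and 8.02 there), are uncertain.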

Other observations

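The tests of an array-wide difference, of the adipocyte share and of exchanged labels were chosen after the results they bear on had been seen, and so was the housekeeping covariate. Stress genes rose in part on the KO-labelled arrays. Of 20 oxidative stress genes 6 rose and 0 fell, or 9 and 2 adjusted over the list alone, with a median change of 0.43 (camera adjusted p = 3.51e-05, and adjusted p = 0.201 with an estimated correlation). The catalase gene Cat rose 21.4-fold, Sod1 5.55-fold, Gstm1 2.36-fold and Gpx4 1.65-fold. Of 21 p53 and cell death genes 5 rose and 1 fell, the same as over the list alone, with a median change of 0.21 (camera adjusted p = 0.00124, and adjusted p = 0.201 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose 8.82-fold, Ccng1 3.94-fold, Casp8 1.76-fold and the survival gene Bcl2l1 1.59-fold. Of 23 immediate early genes 6 rose and 0 fell, the same as over the list alone, with a median change of 0.05 (camera adjusted p = 0.000879, and adjusted p = 0.201 with an estimated correlation). Klf6 rose 4.05-fold and Zfp36, Dusp1 and Ccn1 2.21-fold, 2.23-fold and 2.53-fold. Of 17 clock genes 3 rose and 0 fell, the same as over the list alone, with a median change of 0.12 (camera adjusted p = 0.00491, and adjusted p = 0.201 with an estimated correlation). Clock rose 3.25-fold, Per1 1.57-fold and Arntl 1.47-fold, and Nr1d2 was 0.37 higher without passing. Relative to the housekeeping genes, which were brighter than these lists, their medians were -0.82, -1.04, -1.19 and -1.13. The oxidative stress and clock lists turned down against other genes with the housekeeping covariate (adjusted p = 0.0169 and 0.0455), which separates the labels completely and so decides nothing here.

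Inflammatory genes had no common direction. Of 28 cytokine and chemokine genes 2 rose and 2 fell, or 2 and 1 adjusted over the list alone, with a median change of -0.35 (camera adjusted p = 0.818) that became 0.02 after quantile normalization. Cxcl9 rose 5.58-fold and Nfkbia 3.72-fold, while Tnf fell by 0.60 and Il6 by 0.48 on the log2 scale (-0.23 and -0.11 against the median probe set). Of 25 interferon response genes 4 rose and 1 fell, the same as over the list alone, with a median change of 0.13 and of -1.12 relative to the housekeeping genes (camera adjusted p = 0.00157, and adjusted p = 0.201 with an estimated correlation). Without probe sets of a mean under 6.83 the list was not called (mean change against other genes 0.24, against 0.33 before, adjusted p = 0.134). Ifi27 rose 5.02-fold, Usp18 1.51-fold and Psmb8 1.48-fold, while Mx1 fell by 0.75 (-0.38 against the median probe set). Of 24 cell cycle genes 0 passed, also over the list alone, with a median change of -0.26 that became 0.07 after centring (camera adjusted p = 0.132, and adjusted p = 0.0263 under fry, pointing down). Of 13 Schwann cell genes 1 rose and 0 fell, or 0 and 0 over the list alone, with a median of -0.20 and a mean of 0.15 (camera adjusted p = 0.727). It pointed down and passed with the housekeeping covariate (adjusted p = 0.025), which separates the labels completely and so decides nothing here. That gene, Scn7a, rose 5.12-fold. Of 10 erythroid genes 3 were measured, too few to test, and 0 passed.

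limma called 13791 probe sets between the labelled groups, and the highest count among the other splits of the 6 arrays into 3 and 3 was 0. Only 1 of the 10 splits, the labelled one, gave as many, and 10 splits are too few for a share under 0.05.

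Messenger RNAs of adipocytes, endothelium, mitochondria and housekeeping genes all read higher on the KO-labelled arrays. A smaller share of adipocytes in the WT-labelled samples would lower markers of the other cell types together. Endothelial markers instead had a median change of 0.86 (quartiles 0.14 and 1.68). T cell markers had a median change of -0.40 (quartiles -0.54 and -0.30), and of -0.07 after centring. Most of their fall was thus shared by all probe sets (median change -0.37) and decides little. The endothelial rise argues against a smaller adipocyte share as the whole cause, but rests on 1 list. Smooth muscle, macrophage and progenitor medians were 0.16, 0.07 and 0.05. A part beside an array-wide difference stays open. Relative to the housekeeping genes the endothelial median was -0.38 and those lists stood at -1.08, -1.17 and -1.19, against 1.36 for adipocyte markers. All other cell-type lists were negative there too. The endothelial, smooth muscle, macrophage and progenitor lists were dimmer than the housekeeping genes (WT-labelled medians of 6.97 to 7.31 against 7.86), so this settles nothing. The balance of signal between classes did differ by label. On KO-labelled arrays 93.8% of housekeeping and 90.7% of ribosomal protein genes read higher, against 35.9% of protein-coding and 5.9% of long noncoding RNA probe sets. Its origin was not tested, and how far an array-wide difference in messenger RNA signal accounts for the rises stays open. Across protein-coding genes, differences between arrays of the same label correlated with the KO minus WT difference of the other arrays. The median size was 0.423, between the bounds of the test, in a range from 0.131 (KO 1 against KO 3) to 0.793 (KO 1 against KO 2) over 6 pairs. The pairs with KO 2 gave 0.793 and 0.765 and the others at most 0.499, so the larger values rested on KO 2. With the housekeeping covariate the adipocyte list no longer stood above other genes (adjusted p = 0.108, pointing down), so an effect of the genotype on adipocytes beyond an array-wide difference cannot be told apart from it, because the housekeeping signal separates the labels completely, from 8.91 to 9.20 on WT-labelled and from 10.06 to 10.74 on KO-labelled arrays.

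Tfg did not read lower on the KO-labelled arrays. If the labels had been exchanged, Tfg would rise more than most genes, but its change lay at the 39.3rd percentile of 3308 protein-coding genes of similar level, whose median change was 0.33, so exchanged and correct labels cannot be told apart. Under housekeeping scaling Tfg changed by -1.11, yet 60325 of 65956 probe sets were called lower there. A probe set outside the deleted exons and Tfg from cells without Cre remain open and were not tested.

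Olfactory receptor genes, 1086 of them, read lower on the KO-labelled arrays. A uniform downward shift of dim probe sets would give them the change of unnamed probe sets of the same level. The median change was -0.817, whereas the lowest of 10000 random lists of such probe sets was -0.533. The class had been chosen after the values were seen, and its members resemble each other, unlike those of random lists. The comparison is therefore descriptive only. The class had a median of 7.47 on WT-labelled arrays against 6.98 for all probe sets, and of 6.67 on KO-labelled arrays against 6.65. Without detection calls these levels do not show signal above background. No biological explanation was tested, and what lowers these signals, snoRNA signals included (median change -0.81), stays open.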
